A study of Mus musculus with 25 samples.

How the data were processed

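Total RNA from 25 plates of 3 mouse embryonic fibroblast lines was isolated with a column kit, amplified and biotin labelled by in vitro transcription and hybridized to whole-genome Affymetrix mouse arrays, 1 array per plate. The authors deposited expression values on a log2 scale, 1 per probe set and array, which their processing notes trace to RMA (background correction, normalization between arrays and summary of the probes) with limma named beside it. No versions are stated there, and the chip definition file is not given in the sources used here. A further deposited table holds log2 ratios to the median of the 3 wild-type vehicle arrays, in which 61.4% of probe sets are 0 on every array. Those had a mean log2 value of 5.31 in the expression table, against 8.97 for the others, so dim values had been floored. The ratios are not plain differences of the expression values, with which they correlated at 0.849 to 0.865 over 17386 probe sets, and the floor and summary behind them are not given in the sources used here. That table was used only as an alternative, over 9522 genes. Deposited values ran from 2.72 to 14.74, replicate arrays correlated at 0.996 to 0.998 across probe sets, and the SD of the difference between replicates was 0.129 to 0.209. Arrays have no counts, so their number limits the precision.

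Groups followed line, agent and hours of treatment. The free-text field of the Tsc1-null samples at 24 h and 12 h gives 14 h and 11 h, while their titles, sources and time labels give 24 h and 12 h, which were used. Of 45101 probe sets, 64 were controls, 34945 named 1 gene, 932 several and 9160 none in the table used here. For 34741 the gene identifier matched the reference, and 59 symbols were updated. The probe set with the highest mean over all arrays was kept for each gene, which gave 18161 genes, 9020 of them with more than 1 probe set. Probe sets of 1 gene were called in opposite directions for 142 and 141 genes in the Tsc2-null and Tsc1-null comparisons with wild type, and for 80 and 89 in the 24 h rapamycin comparisons. Listed genes that no probe set names alone were not analysed here.

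limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 11 groups to all 25 arrays (14 residual degrees of freedom, with 7.08 prior degrees of freedom and a prior SD of 0.106). Its two-sided moderated test was applied to each null line against wild type, to the null lines against each other, to each rapamycin time against the vehicle of its line and to the interactions of line and rapamycin, with an F test over the 4 times. P-values were adjusted by Benjamini-Hochberg over genes within a comparison, with a threshold of 0.05. The wild-type littermate design, the tests, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. Lists covered glycolysis and glucose uptake, pentose phosphate pathway, HIF targets outside glycolysis, sterol synthesis and uptake, fatty acid synthesis and desaturation, ATF4 targets with amino acid synthesis and one-carbon metabolism, cytosolic aminoacyl-tRNA synthetases, lysosome and autophagy, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, oxidative phosphorylation and TCA cycle, cell cycle, p53 targets, FOXO targets and receptor feedback, serum response and immediate early genes, interferon response, extracellular matrix and fibroblast genes, smooth muscle and myofibroblast markers, markers of epithelium, endothelium, macrophages, skeletal muscle, adipocytes and neural cells, and sex-linked genes. The sex-linked list had 4 measured genes, under the minimum of 5, and got no list test. The other 24 were tested with camera of limma, each against all other genes, with a preset correlation of 0.01 between genes, adjusted over lists, and again with the correlation estimated from the data. fry of limma, which asks whether a list's genes move on balance in 1 direction and compares it with no other genes, was an alternative.

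Named genes were a fixed set (the TSC genes, metabolic, p53, growth factor receptor and sex-linked genes), the 2 members with the smallest p per list and main comparison, the 4 largest rises and 4 largest falls per main comparison among called genes whose groups did not overlap, the 6 largest of each intersection, the 3 largest rises and falls at 2 h and the 4 smallest F-test p. Members of lists that were not called could be left out, and predicted genes were passed over. The main comparisons were each null line against wild type and 24 h of rapamycin in each null line. Intersections were set beside the count of independent lists and the count in 100 simulations of unchanged groups with the same shared arrays. Their list members were tested with Fisher's exact test.

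Alternatives fixed in advance were quantile normalization, arrays centred on their medians, 64 added to the linear value, the dimmest 40% of genes left out, the mean of all probe sets of a gene, every probe set tested, eBayes with trend and robust, array weights, the replicate number as a block, only the groups compared, each array left out in turn, the 24 h interaction alone, camera with an estimated correlation, and fry. Chosen after seeing the data were the p53 target list mean with each member left out, the deposited ratio table and the interquartile range of each array as a covariate, since the first axis of the residuals held 30.0% of their variance and correlated at 0.992 with array spread. Simulated data with the spread of these arrays held 50 genes changed by each of 0.3, 0.5, 1 and 2 (log2). Of these 3 against 3 recovered 36%, 86%, 100% and 100%, with 9 false calls (5.3% of calls). For 2 against 3 it was 30%, 80%, 100% and 100%, with 11 (6.6%). Real rates may differ. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.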

Results

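Messenger RNA was measured on 25 whole-genome Affymetrix mouse arrays, each holding RNA from 1 plate of 1 of 3 immortalized mouse embryonic fibroblast lines. The wild-type line (Tsc2+/+ p53-/-) and the Tsc2-null line (p53-/-) came from littermates. The Tsc1-null line kept p53 and was immortalized by the 3T3 protocol. Tsc1 and Tsc2 encode the partners of the TSC complex, which holds back the growth-promoting kinase complex mTORC1. Cells at 70% confluence in 10 cm plates were serum starved for 24 h with vehicle (DMSO) or with 20 nM rapamycin, an mTORC1 inhibitor, for 2, 6, 12 or 24 h. Vehicle groups held 3 arrays in each line, and the 8 rapamycin groups, all from the null lines, held 2 arrays each. No wild-type rapamycin array was used here. Array medians lay between 6.26 and 6.41 on the log2 scale, and the number of arrays limits the precision. Replicates were plates of 1 line, so p-values measured the spread between plates and not between independently derived lines. Levels below are log2 values with the SD, differences carry the fitted standard error (SE), and p-values are adjusted. On the probe set kept for each gene, the groups of a gene whose call is reported did not overlap in any 2-group comparison, except for Fasn between the null lines.

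The targeted genes were read first as a check of the labels. Tsc1 stood at 8.19 ± 0.12 in wild type, 8.77 ± 0.09 in Tsc2-null and 7.11 ± 0.24 in Tsc1-null cells under vehicle (n = 3 each), a difference of -1.08 (SE 0.12) between Tsc1-null and wild type with adjusted p = 6.4e-08. The other Tsc1 probe sets gave -0.54 (adjusted p = 3.7e-06) and 0.20 (adjusted p = 0.13) in that comparison. Tsc2, read by 1 probe set, stood at 9.70 ± 0.03 in wild type, 9.49 ± 0.04 in Tsc2-null and 9.69 ± 0.04 in Tsc1-null cells. The Tsc2 difference of -0.21 (SE 0.08) in the Tsc2-null line had adjusted p = 0.042. That call was lost without wild-type vehicle replicate 1, 2 or 3 (0.104, 0.0625 and 0.0776) and without Tsc2-null vehicle replicate 1, 2 or 3 (0.0981, 0.0534 and 0.111). Whether these probe sets lie in the deleted parts is not given in the sources used here, so neither gene checks the genotype labels. Sex-linked genes separated the lines. Xist, the RNA that silences an X chromosome, stood at 6.79 ± 0.06 in wild type, 6.83 ± 0.14 in Tsc2-null and 10.59 ± 0.40 in Tsc1-null cells. The Y-linked Eif2s3y stood at 8.87 ± 0.11, 9.14 ± 0.02 and 3.70 ± 0.27 in the same order. Uty, also Y-linked, was lower in Tsc1-null than in wild-type cells by a difference of -3.04 (SE 0.20, adjusted p = 1.3e-11). Uty differed by -0.47 (adjusted p = 0.055) and Eif2s3y by 0.27 (adjusted p = 0.061) between Tsc2-null and wild type, calls gained without wild-type vehicle replicate 3 (0.0254) and replicate 1 (0.0381). Kdm5d was lower in both null lines, by -1.25 in Tsc2-null (adjusted p = 3.6e-10) and -1.12 in Tsc1-null cells (adjusted p = 2.7e-09). Its other probe sets gave -4.34 and -4.54 (adjusted p = 1e-18 and 4.6e-19) and -0.04 and -0.13 (adjusted p = 0.77 and 0.27) in the same order. The size of its difference thus depends on the probe set. The sex of the embryos is not given in the sources used here.

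The comparison of Tsc2-null with wild-type cells under vehicle asked what differed when the TSC complex lacked Tsc2, in lines that both lacked p53. Genes of glucose use were higher in the Tsc2-null line. Hk2, the first enzyme of glycolysis, rose from 8.67 ± 0.12 to 10.88 ± 0.09 (SD, n = 3 each), a 4.63-fold difference. The lactate exporter Slc16a3 rose from 6.05 ± 0.18 to 11.49 ± 0.05, from a wild-type level near background. Interferon-response genes were lower, with Ifit1 falling from 11.86 ± 0.09 to 5.87 ± 0.15, and so were serum-response genes such as Egr1, which fell from 11.90 ± 0.04 to 7.55 ± 0.08. Of 18 measured genes of glycolysis and glucose uptake, 18 rose (median log2 difference 1.75, camera adjusted p = 1.39e-14, and 0.00487 with an estimated correlation). Among them were Aldoc (4.24), the phosphofructokinase Pfkp (2.30), the pyruvate dehydrogenase kinase Pdk1 (2.15) and the glucose transporter Slc2a1 (1.60). Of 18 other targets of the hypoxia-inducible factor HIF, 15 rose and 1 fell (median 1.10, adjusted p = 1.35e-08, and 0.0331 with an estimated correlation). They included the prolyl hydroxylases Egln3 (3.26, SE 0.08) and P4ha2 (2.75), the growth factor Vegfa (0.47) and the mTORC1 inhibitor Ddit4 (0.96), and Hif1a itself was 0.51 higher. Fatty acid synthesis genes rose in 12 of 16 and fell in 3 (median 0.49, adjusted p = 0.00321), with adjusted p = 0.326 with an estimated correlation. Srebf1, a transcription factor of lipid synthesis, was 0.84 (SE 0.06) higher, Acss2 0.78, the desaturase Scd1 0.61 and the fatty acid synthase gene Fasn 0.52. Scd2 differed by -0.04 (adjusted p = 0.77), with its other probe sets at -0.14 (adjusted p = 0.14) and -0.22 (adjusted p = 0.019). Lysosome and autophagy genes rose in 21 of 31 and fell in 4 (median 0.34, adjusted p = 0.000101, and adjusted p = 0.245 with an estimated correlation). The sialidase Neu1 (2.18) and the proton pump subunit Atp6v1h (1.90) were among them.

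Interferon-response genes fell in 20 of 20 (median -2.18, adjusted p = 6.79e-18, and 0.00487 with an estimated correlation), and serum-response and immediate early genes in 17 of 20 (median -1.16, adjusted p = 7.02e-11, and 0.00184 with an estimated correlation). The phosphatase Dusp6 fell beside Egr1, at -4.29 (SE 0.10). Extracellular matrix and fibroblast genes fell in 17 and rose in 5 of 29, 17 and 6 when adjusted over the list alone (median -0.72, adjusted p = 2.41e-05, and adjusted p = 0.092 with an estimated correlation). The surface glycoprotein Thy1 (-3.96) and the crosslinking enzyme Loxl1 (-4.05) were among them. Of 12 smooth muscle markers, 5 fell and 2 rose (median -0.09, mean -0.64, adjusted p = 0.0274, and adjusted p = 0.092 with an estimated correlation). The contractile gene Acta2 fell from 13.74 ± 0.06 to 11.90 ± 0.02. Ribosome biogenesis genes and MYC targets fell in 17 of 29 and rose in 0, with 18 lower when adjusted over the list alone (median -0.29, adjusted p = 3.77e-05, and adjusted p = 0.218 with an estimated correlation). Myc differed by -2.56 (SE 0.08) and the polyamine enzyme Odc1 by -1.51. Ribosomal protein and translation genes fell in 9 of 19, 10 when adjusted over the list alone (median -0.17, adjusted p = 0.00838, and adjusted p = 0.203 with an estimated correlation). Oxidative phosphorylation and TCA cycle genes rose in 15 of 27 and fell in 6, with 16 higher when adjusted over the list alone (median 0.23, adjusted p = 0.0259, and adjusted p = 0.326 with an estimated correlation). Cell cycle genes rose in 22 of 29 and fell in 4, with 24 and 4 when adjusted over the list alone (median 0.58, adjusted p = 8.34e-05, and adjusted p = 0.44 with an estimated correlation). The mitotic kinase Bub1 rose by 1.40 (SE 0.10), while Ccnd1, the G1 cyclin, fell with a difference of -4.20. Lists not called were sterol synthesis (9 members higher and 5 lower of 20, adjusted p = 0.335), ATF4 targets with amino acid synthesis (11 and 7 of 23, adjusted p = 0.191), pentose phosphate pathway (4 and 2 of 8, adjusted p = 0.567), aminoacyl-tRNA synthetases (4 and 9 of 19, adjusted p = 0.129), FOXO targets (4 and 10 of 19, adjusted p = 0.151) and p53 targets. The p53 targets split into 8 higher and 8 lower of 19, with a median of 0.16, a mean of -0.07 and a camera direction of up (adjusted p = 0.862). Markers of other lineages were not called, with adjusted p from 0.236 for neural and glial to 0.744 for epithelium and endothelium, 0.607 for macrophage and for skeletal muscle and 0.259 for adipocyte lists. The epithelium list had a median of -0.04, a mean of 0.28 and a camera direction of up.

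Other fixed genes included Asns, the asparagine synthetase, which fell from 12.76 ± 0.02 to 11.73 ± 0.04, and Mthfd2, a mitochondrial folate enzyme, which was 0.76 higher in the Tsc2-null line. The sterol regulator gene Srebf2 (-0.27, adjusted p = 0.0057) and the sterol sensor gene Insig1 (-0.39) were lower. Sqle, the squalene epoxidase, differed by -0.04 (adjusted p = 0.77), the cystine transporter gene Slc7a11 by 0.02 (adjusted p = 0.93) and the coactivator gene Ppargc1a by -0.16 (adjusted p = 0.15). Another probe set of Slc7a11 was 0.50 higher (adjusted p = 0.024) and 1 of the other 4 of Ppargc1a was lower, at -0.23 (adjusted p = 0.019). Pdgfrb, a platelet-derived growth factor receptor, fell from 12.31 ± 0.08 to 9.84 ± 0.09. Pdgfra differed by -0.27 (adjusted p = 0.0095), a call lost without wild-type vehicle replicate 1 (0.0962) or Tsc2-null vehicle replicate 3 (0.0508). It was not made on its other probe sets (-0.04 and -0.09, adjusted p = 0.76 and 0.52). The p53 targets Cdkn1a (0.36) and Mdm2 (0.61) were higher and the lysosomal glycoprotein gene Gpnmb (-0.48) was lower. Stk26 (to 11.94 ± 0.04), Cxcl15 (to 12.43 ± 0.03), Rnf128 (to 11.60 ± 0.03) and Ctla2a (to 10.84 ± 0.06) rose from wild-type levels near background, 4.11 to 5.26. The retinoic acid binding protein gene Crabp1 (from 13.26 ± 0.02) and the growth factor Fgf7 (from 11.29 ± 0.04) fell to near background, and the chemokine Ccl5 fell from 12.34 ± 0.06 to 7.16 ± 0.11. In all, 8178 of 18161 genes passed, 4295 higher and 3883 lower, and 1674 of them differed at least 2-fold. Genotype cannot be told apart from line here.

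**Figure D1:**
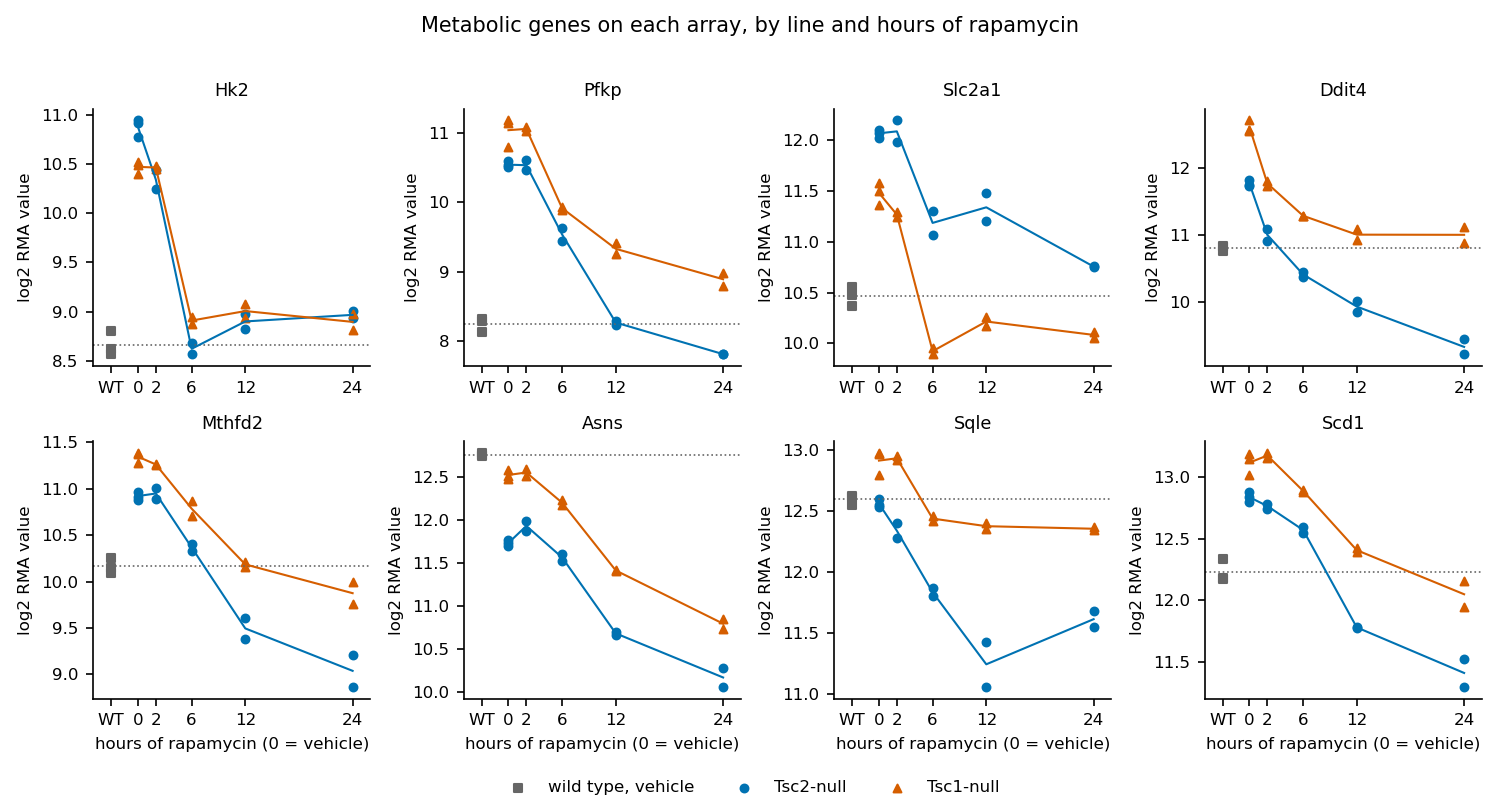
Log2 expression (vertical axes) of Hk2, Pfkp, Slc2a1, Ddit4, Mthfd2, Asns, Sqle and Scd1 on every array against hours of rapamycin (horizontal axes). Squares are wild type, circles Tsc2-null and triangles Tsc1-null, lines join group means and the dotted line is the wild-type mean; Hk2 went from 10.88 to 8.97 in Tsc2-null and from 10.47 to 8.90 in Tsc1-null cells after 24 h, beside 8.67 in wild type.

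The comparison of Tsc1-null with wild-type cells asked the same of the other partner, in a line that also differed in p53 and immortalization. Hypoxia-response and glucose-use genes were higher in the Tsc1-null line. Car9, a carbonic anhydrase, rose from 6.01 ± 0.23 to 10.68 ± 0.07 (SD, n = 3 each), from a wild-type level near background, and Hk2 from 8.67 ± 0.12 to 10.47 ± 0.06, which was 3.50-fold. The mitochondrial coactivator gene Ppargc1a rose from 5.21 ± 0.07 to 9.92 ± 0.16, from a wild-type level near background. Smooth muscle genes were lower, with Acta2 falling from 13.74 ± 0.06 to 9.49 ± 0.12. Targets of HIF outside glycolysis rose in 16 of 18 and fell in 1 (median 1.75, adjusted p = 1.56e-12, and 0.00849 with an estimated correlation), among them Egln3 (3.26), Ddit4 (1.80) and Vegfa (1.02). Glycolysis genes rose in 14 of 18 and fell in 2, with 15 and 2 when adjusted over the list alone (median 1.00, adjusted p = 2.11e-08, and 0.0286 with an estimated correlation). Pfkp (2.80, SE 0.09), Pdk1 (2.32) and Slc2a1 (1.02) were among them. ATF4 targets and amino acid synthesis genes rose in 20 of 23 and fell in 1 (median 0.71, adjusted p = 2.69e-10, and 0.0457 with an estimated correlation). The cysteine synthesis gene Cth rose from 8.60 ± 0.06 to 11.31 ± 0.05, the lipoprotein receptor gene Vldlr was 4.64 higher, Mthfd2 1.18 and Slc7a11 1.24 (2.62 on its other probe set), while Asns was lower (-0.24, adjusted p = 0.0047). Oxidative phosphorylation and TCA cycle genes rose in 18 of 27 and fell in 2 (median 0.28, adjusted p = 2.25e-05, and 0.0457 with an estimated correlation), with Ndufa9 at 0.98.

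Sterol synthesis genes rose in 15 of 20 and fell in 1 (median 0.31, adjusted p = 1.17e-05, and adjusted p = 0.151 with an estimated correlation). Ebp (1.05), Sc5d (1.05), Insig1 (0.41) and Sqle (0.32) were among them, and Srebf2 differed by 0.16 (adjusted p = 0.11). Fatty acid synthesis genes rose in 12 of 16 and fell in 1 (median 0.38, adjusted p = 0.000136, and adjusted p = 0.174 with an estimated correlation). Acss2 was 1.27 higher, Scd1 0.89 and Elovl6 0.83, and the member that fell was Srebf1 (-0.37). Scd2 differed by -0.01 (adjusted p = 0.96), with its other probe sets at -0.04 (adjusted p = 0.71) and 0.69 (adjusted p = 7.1e-08). Fasn was 0.30 higher (adjusted p = 0.0058), a call lost without Tsc1-null vehicle replicate 1 (0.0579). Lysosome genes rose in 20 of 31 and fell in 5 (median 0.38, adjusted p = 7.02e-05, and adjusted p = 0.174 with an estimated correlation), with the galactosidase gene Gla at 2.04 and Rragd, a lysosomal GTPase gene, at 2.42. Pentose phosphate genes rose in 6 of 8 and fell in 2 (median 0.45, adjusted p = 0.0337, and adjusted p = 0.251 with an estimated correlation), a call lost without Tsc1-null vehicle replicate 3 (0.0528). Ribosome biogenesis genes fell in 24 of 29, 27 when adjusted over the list alone (median -0.52, adjusted p = 7.5e-10, and 0.0457 with an estimated correlation), with Myc at -1.45 and Odc1 at -1.74. Serum-response genes fell in 13 of 20 and rose in 2 (median -0.77, adjusted p = 8.83e-07, and 0.00849 with an estimated correlation), with Egr1 at -5.17. Interferon-response genes fell in 16 of 20 and rose in 1 (median -1.33, adjusted p = 1.92e-10, and 0.0286 with an estimated correlation), with Ifit1 at -4.88 and Ifit3 at -4.15. Matrix and fibroblast genes fell in 19 of 29 and rose in 4, with 20 lower when adjusted over the list alone (median -0.46, adjusted p = 4.02e-06, and 0.0457 with an estimated correlation). Smooth muscle markers fell in 7 of 12, 8 when adjusted over the list alone (median -0.40, adjusted p = 7.41e-05, and 0.00849 with an estimated correlation), with Tagln at -4.87. Cell cycle genes fell in 22 of 29 and rose in 1, with 23 lower when adjusted over the list alone (median -0.61, adjusted p = 1.73e-08, and adjusted p = 0.174 with an estimated correlation). Ccnd1 (-3.89) and the nucleotide reductase subunit gene Rrm2 (-2.22) were among them.

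Lists not called in the Tsc1-null line were aminoacyl-tRNA synthetases (8 higher and 3 lower of 19, adjusted p = 0.139), ribosomal proteins (0 and 6 of 19, adjusted p = 0.154), p53 targets (9 and 6 of 19, adjusted p = 0.222) and FOXO targets (6 and 8 of 19, adjusted p = 0.657). Other-lineage lists were not called either, with adjusted p from 0.271 for neural and glial to 0.786 for endothelium and macrophage markers. Their median and mean differed in sign for epithelium (0.01 and -0.37), endothelium (0.02 and -0.01) and macrophage markers (-0.07 and 0.05). Cdkn1a, a cell cycle inhibitor gene and p53 target, was 1.03 (SE 0.08) higher, Mdm2 0.27 and Pdgfra 0.55, while Pdgfrb (-0.88) and Gpnmb (-0.44) were lower. Hif1a was 0.21 higher (adjusted p = 0.022), a call lost without wild-type vehicle replicate 3 (0.0893) or Tsc1-null vehicle replicate 1 (0.141). Its other probe sets differed by 0.68 (adjusted p = 3.4e-06), 0.68 (adjusted p = 2.4e-07) and 0.19 (adjusted p = 0.081). The surface glycoprotein gene Cd24a (to 12.66 ± 0.14), the transcriptional coactivator gene Eya4 (to 10.69 ± 0.07), the amino acid transporter gene Slc7a2 (to 10.74 ± 0.08) and the desmosomal p53 target Perp (to 10.45 ± 0.25) rose from wild-type levels near background, 4.09 to 4.98. The matrix genes Postn (from 12.15 ± 0.10) and Ccn2 (from 10.93 ± 0.19) and the amino acid transporter gene Slc38a4 (from 11.08 ± 0.01) fell to near background, and Dlk1 fell from 12.62 ± 0.06 to 6.67 ± 0.18. In all, 7646 genes passed, 3870 higher and 3776 lower, and 1467 of them differed at least 2-fold.

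Set against each other under vehicle, the null lines differed most in cell cycle genes, which were lower in Tsc1-null cells for 26 of 29 and higher for 2. Their median was -1.04 (adjusted p = 2.25e-13), with adjusted p = 0.267 with an estimated correlation. ATF4 targets were higher in Tsc1-null cells for 18 of 23 and lower for 3, with 19 and 3 when adjusted over the list alone (median 0.64, adjusted p = 1.47e-06, and adjusted p = 0.285 with an estimated correlation), such as Asns (0.79), Slc7a11 (1.22) and Mthfd2 (0.42). Interferon-response genes were higher for 14 of 20 and lower for 1, with 15 higher when adjusted over the list alone (median 0.64, adjusted p = 5.57e-06, and adjusted p = 0.267 with an estimated correlation). Sterol genes (14 higher and 3 lower of 20, median 0.31, adjusted p = 0.00928) and tRNA synthetases (12 and 1 of 19, median 0.31, adjusted p = 0.0041) were higher, each with adjusted p = 0.518 with an estimated correlation. Glycolysis genes were lower for 10 of 18 and higher for 5 (median -0.27, adjusted p = 0.0304, and adjusted p = 0.518 with an estimated correlation), a call lost without Tsc1-null vehicle replicate 3 (0.0549). Of the fixed genes Ppargc1a stood 4.87 (SE 0.08) higher, over a Tsc2-null level near background, and Srebf1 differed by -1.21, while Scd2 (0.03, adjusted p = 0.83), Gpnmb (0.04, adjusted p = 0.73), Kdm5d (0.14, adjusted p = 0.32) and Tsc2 (0.20, adjusted p = 0.058) did not pass. In all 7879 genes passed, 3762 higher and 4117 lower in Tsc1-null cells. Against wild type, 2204 genes were higher in both null lines and 2096 lower in both, where independent lists would share 915.2 and 807.3, and 642 were higher in Tsc2-null but lower in Tsc1-null cells, as many as the reverse. The same wild-type arrays entered both comparisons. The correlation across genes, which are not independent replicates, was 0.468, against 0.511 in simulations of unchanged groups sharing those arrays, while the covariance was 0.214 against 0.0052. Part of the excess may come from the shared controls, since 3 control arrays cannot be divided into sets of at least 2, and it is not called a shared effect.

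**Figure D2:**
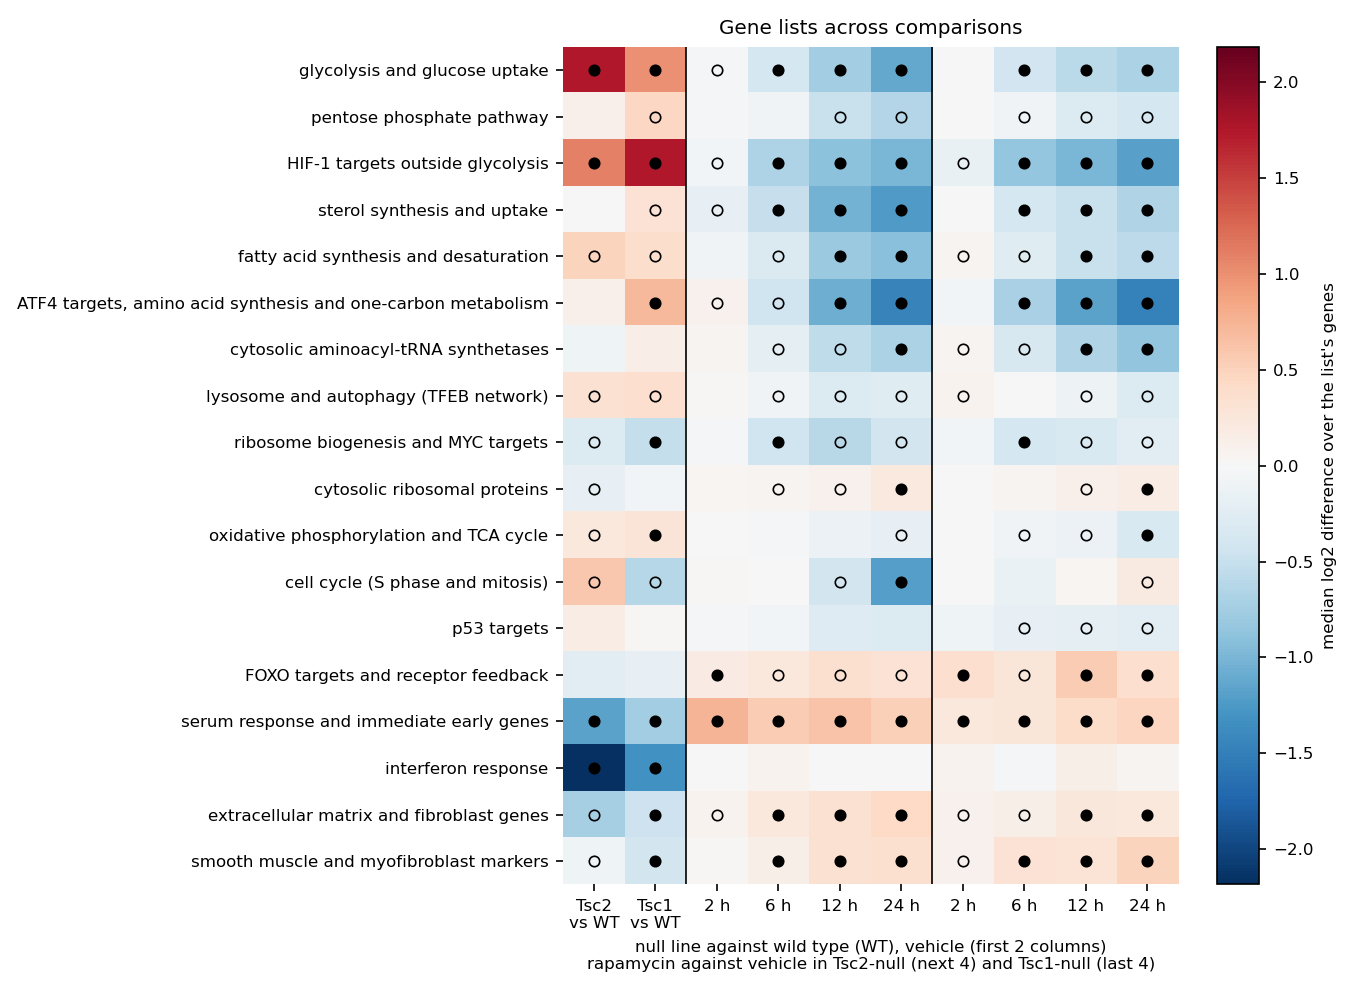
Median log2 difference (colour scale) of the genes of 18 fixed lists (vertical axis) in 10 comparisons (horizontal axis: each null line against wild type, then hours of rapamycin in Tsc2-null and in Tsc1-null cells). Filled circles mark lists called also with an estimated correlation and open circles those called with the preset correlation alone; glycolysis had medians of 1.75 and 1.00 against wild type and -1.12 and -0.69 after 24 h of rapamycin.

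Each rapamycin time was compared with the 1 vehicle group of its line. Handling of the plates was thus not separated from rapamycin at 2, 6 or 12 h. At 2 h the immediate early genes rose in both null lines. The transcription factor gene Egr1 rose by 2.89 (SE 0.09, n = 2 against 3) in Tsc2-null and 2.36 (SE 0.09) in Tsc1-null cells, and Dusp6 from 5.88 ± 0.18 to 7.84 ± 0.08 and from 6.34 ± 0.20 to 7.83 ± 0.07. Ccn2 rose by 1.82 in Tsc2-null cells, and the ubiquitin ligase gene Fbxo32 from 7.69 ± 0.04 to 9.19 ± 0.03 in Tsc1-null cells. The stress gene Ddit4 fell in both, at -0.77 (SE 0.09) and -0.84 (SE 0.09). The other largest falls were Ppp1r3b (-1.08), the glycolytic regulator gene Pfkfb3 (-0.96) and Noct (-0.90) in Tsc2-null cells, and the hormone gene Fgf21 (-1.34), Btg2 (-1.20) and Mfsd2a (-0.91) in Tsc1-null cells. Hk2 differed by -0.54 in Tsc2-null cells (adjusted p = 0.0012, and 0.0648 without 2 h replicate 1), while in Tsc1-null cells Vegfa fell with -0.57 and Cdkn1a with -0.51. Myc rose by 0.94 and 0.72. Serum-response genes rose in 11 of 20 in Tsc2-null (median 0.73, adjusted p = 1.56e-34, and 1.95e-06 with an estimated correlation) and 8 of 20 in Tsc1-null cells (median 0.23, adjusted p = 1.24e-11, and 0.0012 with an estimated correlation). FOXO targets, which include growth factor receptor feedback genes, rose in 6 of 19, 8 when adjusted over the list alone (median 0.17, adjusted p = 1.6e-10, and 0.0415 with an estimated correlation), and in 9 of 19, 12 when adjusted over the list alone (median 0.37, adjusted p = 3.89e-17, and 0.00535 with an estimated correlation).

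Smaller list shifts at 2 h were called with the preset correlation alone. In Tsc2-null cells these were sterol synthesis (4 lower and 1 higher of 20, 11 and 1 when adjusted over the list alone, median -0.18, adjusted p = 1.87e-08, and adjusted p = 0.12 with an estimated correlation), matrix genes (4 of 29 higher, 7 when adjusted over the list alone, median 0.08, adjusted p = 7.48e-06, and adjusted p = 0.12 with an estimated correlation) and glycolysis (3 of 18 lower, median -0.04, adjusted p = 0.00409, and adjusted p = 0.412 with an estimated correlation). HIF targets had 3 lower and 2 higher of 18, 5 and 2 when adjusted over the list alone (median -0.06, adjusted p = 0.00703, and adjusted p = 0.415 with an estimated correlation), lost without 2 h replicate 1 (0.119). ATF4 targets had 0 of 23 called (median 0.09, adjusted p = 0.0483, and adjusted p = 0.655 with an estimated correlation), lost without 2 h replicate 2 (0.571) or vehicle replicate 1 (0.0767) or 2 (0.086). Calls were gained for synthetases without 2 h replicate 1 (0.0107) or vehicle replicate 1 (0.0218), ribosomal proteins without 2 h replicate 1 (0.0455) or vehicle replicate 3 (0.049), lysosome genes without 2 h replicate 1 (0.0151), fatty acid genes without vehicle replicate 3 (0.0119), ribosome biogenesis without 2 h replicate 2 (0.00992) and epithelium markers without vehicle replicate 2 (0.0471). In Tsc1-null cells HIF targets fell in 4 of 18, 9 when adjusted over the list alone (median -0.17, adjusted p = 1.8e-07, and adjusted p = 0.0526 with an estimated correlation). Lysosome genes (2 of 31 higher, 3 when adjusted over the list alone, adjusted p = 0.00013, and adjusted p = 0.353 with an estimated correlation), matrix genes (2 of 29 higher, 7 when adjusted over the list alone, adjusted p = 0.000124, and adjusted p = 0.154 with an estimated correlation) and smooth muscle markers (1 of 12 higher, adjusted p = 0.0133, and adjusted p = 0.0526 with an estimated correlation) were called with medians of 0.08, 0.10 and 0.10. Synthetases (1 of 19 higher, median 0.07, adjusted p = 0.00754) and fatty acid genes (1 of 16, median 0.06, adjusted p = 0.0168) had adjusted p = 0.7 with an estimated correlation. The first was lost without Tsc1-null vehicle replicate 3 (0.0986), and the other without that array (0.127) or 2 h replicate 2. Over all genes 400 passed in Tsc2-null cells (184 higher, 216 lower) and 592 in Tsc1-null cells (352 higher, 240 lower). With another setting the Tsc2-null count was 606 (quantile normalization), 721 (array spread as a covariate) or 228 (only the groups compared). The Tsc1-null count was 934, 1136 and 234 in the same order, 1355 with array weights and 378 with the replicate block. Of the genes called at 2 h, 98 were higher in both lines and 94 lower in both, against 3.6 and 2.9 of independent lists. The Tsc2-null count was 248, 239 and 241 without vehicle replicates 1, 2 and 3, and the Tsc1-null count was 342 without vehicle replicate 2. The share of higher calls in Tsc1-null cells was 59.5%, against 49.3% after quantile normalization, 65.2% after median centring and 44.9% with array spread as a covariate.

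HIF target, glycolysis, sterol, ribosome biogenesis, ATF4 target and fatty acid list means were lower in both lines at 6 and 12 h. Hk2 fell at 6 h with -2.26 (SE 0.09, n = 2 against 3) in Tsc2-null and -1.56 in Tsc1-null cells, and Pfkp went from -1.01 and -1.13 at 6 h to -2.28 and -1.71 at 12 h. Asns differed by -0.17 at 6 h (adjusted p = 0.11) and by -1.05 at 12 h in Tsc2-null cells, and fell with -1.11 at 12 h in Tsc1-null cells. Its 6 h difference there was -0.32, with adjusted p = 0.0027 and 0.0505 without 6 h replicate 2. Sqle fell in Tsc2-null cells with -0.73 and -1.32 and in Tsc1-null cells with -0.48 and -0.54. HIF targets at 6 h fell in 16 of 18 in Tsc2-null (median -0.67, adjusted p = 1.85e-18, and 0.00467 with an estimated correlation) and 18 of 18 in Tsc1-null cells (median -0.85, adjusted p = 2.96e-28, and 0.000552 with an estimated correlation). Glycolysis genes fell in 11 of 18 in each line, 13 and 12 when adjusted over the list alone (medians -0.38 and -0.42, adjusted p = 5.7e-11 and 5.23e-09, and 0.0163 and 0.0195 with an estimated correlation). Sterol genes fell in 17 and 15 of 20 (medians -0.50 and -0.39, adjusted p = 1.7e-13 and 2.62e-13, and 0.0266 and 0.0195 with an estimated correlation). Ribosome biogenesis genes fell in 20 and 19 of 29, 21 and 20 when adjusted over the list alone (medians -0.44 and -0.38, adjusted p = 2.8e-11 and 1.71e-10, and 0.0376 and 0.0387 with an estimated correlation). ATF4 targets fell at 6 h in 14 of 23 in Tsc2-null (median -0.43, adjusted p = 1.24e-09, and adjusted p = 0.0562 with an estimated correlation) and 21 of 23 in Tsc1-null cells (median -0.72, adjusted p = 1.28e-20, and 0.012 with an estimated correlation). At 12 h they fell in 20 and 22 of 23 (medians -1.06 and -1.16, adjusted p = 3.83e-16 and 2.72e-33, and 0.015 and 0.00141 with an estimated correlation). The tRNA synthetases fell at 12 h in 17 and 16 of 19, and rose in 1 and 2 (medians -0.56 and -0.65, adjusted p = 3.6e-09 and 1.8e-13, and adjusted p = 0.0666 and 0.0261 with an estimated correlation). Serum-response genes stayed higher than under vehicle at 12 h, in 12 and 11 of 20 (medians 0.62 and 0.39, adjusted p = 1.46e-07 and 9.03e-08, and 0.0112 and 0.00316 with an estimated correlation). Fatty acid genes fell at 12 h in 14 and 13 of 16 (medians -0.81 and -0.49, adjusted p = 3.56e-11 and 1.54e-09, and 0.0202 and 0.0275 with an estimated correlation), with Fasn at -0.87 and -0.57. Matrix genes rose at 12 h in 20 and 17 of 29 (medians 0.33 and 0.26, adjusted p = 3.37e-07 and 9.42e-08, and 0.0313 and 0.0261 with an estimated correlation), and smooth muscle markers in 7 and 6 of 12 (medians 0.34 and 0.31, adjusted p = 0.000729 and 1.49e-06, and 0.0112 and 0.00141 with an estimated correlation). FOXO targets rose at 12 h in 11 and 13 of 19 (medians 0.36 and 0.55, adjusted p = 1.37e-05 and 7.19e-08, and adjusted p = 0.0735 and 0.0275 with an estimated correlation). Lysosome genes fell at 12 h in 17 and 12 of 31 and rose in 5 and 4 (adjusted p = 0.000714 and 0.0116, and adjusted p = 0.238 and 0.385 with an estimated correlation).

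Cell cycle genes fell at 12 h in 16 of 29 and rose in 4 in Tsc2-null cells (median -0.41, adjusted p = 6.57e-05, and adjusted p = 0.317 with an estimated correlation), while in Tsc1-null cells 9 rose and 5 fell (median 0.04, adjusted p = 0.573). The ribosomal protein list was called higher in Tsc2-null cells at 6 h with 3 of 19 (median 0.07, adjusted p = 0.0332, and adjusted p = 0.259 with an estimated correlation), lost without 6 h replicate 1 (0.0614) or 2 (0.05) or vehicle replicate 1 (0.0667). At 12 h it was called in both, with 6 and 5 of 19 (medians 0.09 and 0.12, adjusted p = 0.0042 and 0.00558, and adjusted p = 0.103 in each with an estimated correlation). Its 12 h median in Tsc2-null cells was -0.0478 in the deposited ratio table. Epithelium markers were called higher in Tsc2-null cells at 12 h, with 4 of 12 (median 0.08, adjusted p = 0.0473, and adjusted p = 0.235 with an estimated correlation), lost without 12 h replicate 2 (0.0686) or vehicle replicate 3 (0.0754). The p53 targets fell in Tsc1-null cells at 12 h in 7 of 19 and rose in 2 (median -0.21, adjusted p = 0.0143, and adjusted p = 0.266 with an estimated correlation), lost without 12 h replicate 1 (0.0767). In Tsc2-null cells calls were gained at 6 h for epithelium markers without 6 h replicate 1 or vehicle replicate 2 (0.0493). Oxidative phosphorylation and pentose phosphate genes were gained without 6 h replicate 1. At 12 h oxidative phosphorylation was gained there without 12 h replicate 1 or vehicle replicate 1 (0.0458) or 2 (0.0375). In Tsc1-null cells calls were gained for cell cycle genes at 6 h without 6 h replicate 1 or vehicle replicate 1 (0.0241). Interferon genes at 12 h (adjusted p = 0.0564) were gained without 12 h replicate 1 or vehicle replicate 3 (0.0371). At 6 h 3870 genes passed in Tsc2-null cells (2108 higher) and 4094 in Tsc1-null cells (1725 higher), and at 12 h 6198 (2988 higher) and 4320 (2193 higher). The Tsc1-null 6 h count was 6488 with array weights. Its share of higher calls was 42.1%, against 53.3% after quantile normalization, 30.2% after median centring and 48.6% with array spread as a covariate. With that covariate 2691 of its 4094 calls kept their direction and call, and 3410 did after quantile normalization.

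After 24 h in the Tsc2-null line, rapamycin lowered genes of amino acid, sterol, fatty acid and glucose metabolism and of the cell cycle. Hk2 fell from 10.88 ± 0.09 (SD, n = 3) to 8.97 ± 0.05 (n = 2), Pfkp from 10.55 ± 0.04 to 7.81 ± 0.01 and Psph, the last enzyme of serine synthesis, from 11.19 ± 0.06 to 8.80 ± 0.03. Bub1 fell from 10.12 ± 0.08 to 7.78 ± 0.09. The contractile gene Tagln rose from 9.69 ± 0.13 to 12.16 ± 0.21. ATF4 targets fell in 21 of 23 and rose in 1 (median -1.46, adjusted p = 4.9e-19, and 0.0108 with an estimated correlation), among them Vldlr (-2.66), Mthfd2 (-1.88), Asns (-1.56) and Slc7a11 (-0.94). Sterol genes fell in 18 of 20 and rose in 1 (median -1.24, adjusted p = 8.23e-17, and 0.0108 with an estimated correlation). Mvd (-1.84), Sc5d (-1.44) and Sqle (-0.95) fell, and Insig1, the member that rose, was 0.41 higher. Glycolysis genes fell in 16 of 18 and rose in 1 (median -1.12, adjusted p = 1.98e-13, and 0.0108 with an estimated correlation), with Slc16a3 at -2.40, Slc2a1 at -1.31 and Pdk1 at -1.13. HIF targets fell in 14 of 18 and rose in 1 (median -0.995, adjusted p = 4.72e-11, and 0.0108 with an estimated correlation), with Ddit4 at -2.43, Higd1a at -1.84 and Vegfa at -0.77, and Hif1a itself at -0.39. Fatty acid genes fell in 15 of 16 (median -0.91, adjusted p = 3.91e-13, and 0.0116 with an estimated correlation), with Acss2 at -2.33, Scd1 at -1.43 and Srebf1 at -0.91, while Fasn fell from 11.64 ± 0.13 to 10.64 ± 0.10. Scd2 differed by -0.27 (adjusted p = 0.018, and 0.105 without vehicle replicate 1 or 0.265 without 24 h replicate 1). Srebf2 differed by 0.18 (adjusted p = 0.13, and 0.0408 without vehicle replicate 1 or 0.013 without 24 h replicate 2), and by 0.29 on another probe set (adjusted p = 0.011). The tRNA synthetases fell in 17 of 19 and rose in 1, with 18 lower when adjusted over the list alone (median -0.70, adjusted p = 4.86e-11, and 0.0407 with an estimated correlation), with Aars at -1.21 and Gars at -1.02.

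Cell cycle genes fell in 26 of 29 and rose in 3 (median -1.20, adjusted p = 3.45e-17, and 0.0411 with an estimated correlation), with Rrm2 at -2.73. Matrix and fibroblast genes rose in 21 of 29 and fell in 2 (median 0.44, adjusted p = 7.34e-08, and 0.0226 with an estimated correlation), with Loxl1 at 1.97 and the protease inhibitor gene Timp3 at 1.64. Smooth muscle markers rose in 6 of 12 and fell in 1 (median 0.35, adjusted p = 0.000237, and 0.0108 with an estimated correlation), with Myl9 at 1.73. Serum-response genes rose in 12 of 20 and fell in 4, with 13 higher when adjusted over the list alone (median 0.51, adjusted p = 1.61e-05, and 0.0108 with an estimated correlation), with Dusp6 at 3.37, Spry2 at 2.20 and Egr1 at 2.04. Ribosomal proteins rose in 12 of 19, 13 when adjusted over the list alone (median 0.21, adjusted p = 0.000115, and 0.0349 with an estimated correlation), with the elongation factor gene Eef2 at 0.64. Pentose phosphate genes fell in 5 of 8 and rose in 2 (median -0.65, adjusted p = 0.00653, and adjusted p = 0.146 with an estimated correlation), with Rpia at -1.46. Ribosome biogenesis genes fell in 21 of 29 and rose in 3, with 22 lower when adjusted over the list alone (median -0.40, adjusted p = 3.31e-06, and adjusted p = 0.104 with an estimated correlation), with Nip7 at -0.92, while Myc rose by 0.65. Lysosome genes fell in 18 of 31 and rose in 5 (median -0.26, adjusted p = 0.000237, and adjusted p = 0.187 with an estimated correlation), with Neu1 at -1.72 and the cathepsin gene Ctsf at 2.11. Oxidative phosphorylation genes fell in 13 of 27 and rose in 2 (median -0.19, adjusted p = 0.0165, and adjusted p = 0.208 with an estimated correlation), with Idh3a at -0.89. FOXO targets rose in 10 of 19 and fell in 2 (median 0.32, adjusted p = 0.00134, and adjusted p = 0.177 with an estimated correlation), with Fbxo32 at 2.30 and the insulin receptor substrate gene Irs2 at 1.47. Interferon genes (4 higher and 3 lower of 20, adjusted p = 0.567) and p53 targets (4 and 10 of 19, adjusted p = 0.133) were not called, though Cdkn1a (-2.06) and Mdm2 (-0.59) fell. Epithelium markers were not called (4 higher and 1 lower of 12, adjusted p = 0.0839) except without 24 h replicate 1 (0.048), and the other lineage lists had adjusted p from 0.479 to 0.951. Tsc1 fell with -0.77 (SE 0.13), and the sex-linked Xist, Eif2s3y, Kdm5d and Uty were not called (adjusted p = 0.77, 0.5, 0.42 and 0.75). Pdgfra rose by 1.28 and Pdgfrb differed by -0.03 (adjusted p = 0.88), Ppargc1a by -0.20 (adjusted p = 0.11) and Gpnmb by -0.37. The metallothionein gene Mt2 rose by 4.02 and Ccn2 by 3.34, while Rspo1 (to 10.10 ± 0.42) and Dusp6 (to 9.25 ± 0.17) rose from levels near background. The fatty acid receptor gene Ffar4 (to 6.00 ± 0.23) and the replication gene Cdc6 (to 6.16 ± 0.25) fell to near background, and Rrm2 fell from 11.68 ± 0.05 to 8.95 ± 0.05. Over all genes 6462 passed, 3170 higher and 3292 lower, and 868 of them changed at least 2-fold.

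After 24 h in the Tsc1-null line, rapamycin lowered ATF4 target, HIF target, glycolysis, sterol and fatty acid genes. Cth fell from 11.31 ± 0.05 (SD, n = 3) to 8.26 ± 0.03 (n = 2), Hk2 from 10.47 ± 0.06 to 8.90 ± 0.11 and Asns from 12.52 ± 0.06 to 10.80 ± 0.08. The contractile gene Acta2 rose from 9.49 ± 0.12 to 11.82 ± 0.01. ATF4 targets fell in 22 of 23 (median -1.47, adjusted p = 3.36e-26, and 0.00314 with an estimated correlation), with Psph at -2.51 and Mthfd2 at -1.47, while Slc7a11 fell from 8.25 ± 0.35 to 6.75 ± 0.10. HIF targets fell in 17 of 18 (median -1.19, adjusted p = 3.4e-19, and 0.00209 with an estimated correlation), with Egln3 at -2.16, the oxidoreductase gene Ero1a at -2.01, Ddit4 at -1.61 and Vegfa at -0.84. Hif1a differed by 0.00 (adjusted p = 0.98). Of its other probe sets 1 fell with -0.45 (adjusted p = 0.00045) and the rest, at -0.01 and -0.22, were not called (adjusted p = 0.97 and 0.1). The tRNA synthetases fell in 17 of 19 and rose in 1 (median -0.86, adjusted p = 1.55e-13, and 0.0217 with an estimated correlation), with Cars at -1.35 and Gars at -1.04. Glycolysis genes fell in 12 of 18, 13 when adjusted over the list alone (median -0.69, adjusted p = 1.67e-10, and 0.0119 with an estimated correlation), with Pfkp at -2.15, Slc2a1 at -1.40 and Pdk1 at -0.91. Sterol genes fell in 19 of 20 (median -0.67, adjusted p = 2.83e-15, and 0.0119 with an estimated correlation), with Sc5d at -1.03, Mvd at -1.01 and Sqle at -0.56. Insig1 differed by -0.27 (adjusted p = 0.021), a call lost without vehicle replicate 1 (0.0681) or 24 h replicate 1 or 2. Fatty acid genes fell in 14 of 16, 15 with 1 higher when adjusted over the list alone (median -0.57, adjusted p = 2.03e-10, and 0.0217 with an estimated correlation), with Acss2 at -1.65, Acsl3 at -1.23, Scd1 at -1.07 and Fasn at -0.55. Scd2 differed by -0.27 (adjusted p = 0.021, and 0.0834 without vehicle replicate 1 or 0.177 without 24 h replicate 1), Srebf1 by -0.16 (adjusted p = 0.079) and Srebf2 by -0.07 (adjusted p = 0.61). Oxidative phosphorylation genes fell in 19 of 27, 20 when adjusted over the list alone (median -0.33, adjusted p = 7.4e-08, and 0.0139 with an estimated correlation), with Idh3a at -1.18, Cyc1 at -0.69 and, outside the electron chain, Ppargc1a at -0.43.

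Smooth muscle markers rose in 8 of 12 (median 0.49, adjusted p = 6.4e-08, and 0.000923 with an estimated correlation), with Myl9 at 2.41. Serum-response genes rose in 11 of 20 and fell in 1 (median 0.47, adjusted p = 3.34e-08, and 0.00312 with an estimated correlation), with Ccn1 at 3.04 and Egr1 at 2.23. FOXO targets rose in 11 of 19 and fell in 1, with 12 higher when adjusted over the list alone (median 0.37, adjusted p = 1.06e-06, and 0.0411 with an estimated correlation), with the growth factor receptor gene Igf1r at 1.44 and Cited2 at 0.94. Matrix genes rose in 14 of 29 and fell in 1, with 17 higher when adjusted over the list alone (median 0.23, adjusted p = 1.39e-06, and 0.0324 with an estimated correlation), with Thbs2 at 1.54 and Thbs1 at 1.45. Ribosomal proteins rose in 10 of 19, 12 when adjusted over the list alone (median 0.17, adjusted p = 3.05e-05, and 0.0217 with an estimated correlation). Cell cycle genes rose in 15 of 29 and fell in 4, with 15 and 5 when adjusted over the list alone (median 0.20, adjusted p = 0.000224, and adjusted p = 0.372 with an estimated correlation), with the replication helicase genes Mcm5 at 1.04 and Mcm7 at 1.03. That call was lost without 24 h replicate 2. Lysosome genes fell in 21 of 31 and rose in 3, with 22 lower when adjusted over the list alone (median -0.31, adjusted p = 7.66e-07, and adjusted p = 0.0784 with an estimated correlation), with Gla at -1.80. Pentose phosphate genes fell in 4 of 8 and rose in 1 (median -0.39, adjusted p = 0.00229, and adjusted p = 0.093 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 29 and rose in 4, with 17 and 5 when adjusted over the list alone (median -0.23, adjusted p = 0.0111, and adjusted p = 0.372 with an estimated correlation), lost without 24 h replicate 1 (0.296), while Myc rose by 1.12. The p53 targets fell in 9 of 19 and rose in 2, with 11 lower when adjusted over the list alone (median -0.23, adjusted p = 0.026, and adjusted p = 0.334 with an estimated correlation), lost without 24 h replicate 1 (0.228) or vehicle replicate 3 (0.0617). Cdkn1a fell with -1.32, and Mdm2 differed by -0.23 (adjusted p = 0.023, and 0.0501 without vehicle replicate 2 or 0.179 without 24 h replicate 1). Interferon genes were not called (4 higher and 4 lower of 20, adjusted p = 0.181), nor were other-lineage lists (adjusted p from 0.275 to 0.859). Tsc1 differed by -0.16 (adjusted p = 0.45), and Xist, Eif2s3y, Kdm5d and Uty were not called (adjusted p = 0.85, 0.56, 0.35 and 0.84). Pdgfra rose by 0.80 and Pdgfrb by 0.71, and Gpnmb fell with -0.30. The activin antagonist gene Fst (to 9.60 ± 0.35) and Plscr2 (to 6.59 ± 0.63) rose from levels near background, and Fgf7 rose by 2.66. Slc7a3 fell with -3.30 and Fabp4 to near background (5.57 ± 0.01). So did the growth factor binding protein gene Igfbp5 (5.88 ± 0.01), but its other probe set gave -0.22 (adjusted p = 0.1). Over all genes 5376 passed, 2109 higher and 3267 lower, and 422 of them changed at least 2-fold.

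Whether the null lines answered rapamycin differently was tested as the interaction of line and treatment. Over the 4 times, 3911 genes differed, and the genes with the smallest p were Id1, Igfbp3, Gsta4 and Col8a1. Id1, an inhibitor of differentiation factors, rose in Tsc2-null cells from 8.57 ± 0.03 (SD, n = 3) to 11.90 ± 0.01 (n = 2) at 24 h. It went from 8.18 ± 0.10 to 7.86 ± 0.16 in Tsc1-null cells (adjusted p = 0.048, and 0.112 or 0.137 without vehicle replicate 1 or 2). Igfbp3 rose by 2.27 in Tsc2-null cells and differed by -0.34 in Tsc1-null cells (adjusted p = 0.0045, and 0.115 without 24 h replicate 1). The glutathione transferase gene Gsta4 rose by 0.68 in one and fell with -1.58 in the other, and the collagen gene Col8a1 rose by 0.39 and 2.61. Tsc2 itself fell in Tsc2-null cells from 9.49 ± 0.04 to 7.98 ± 0.18 and stood at 9.69 ± 0.04 and 9.68 ± 0.15 in Tsc1-null cells, a difference between the lines of 1.51 (SE 0.13, adjusted p = 1.8e-08). Cell cycle genes moved apart most, with 26 of 29 higher and 1 lower in the Tsc1-null response relative to Tsc2-null (median 1.49, adjusted p = 1.76e-32, and adjusted p = 0.0573 with an estimated correlation). Sterol genes (14 higher and 1 lower of 20, median 0.47, adjusted p = 1.16e-07, and adjusted p = 0.293 with an estimated correlation), glycolysis genes (7 and 1 of 18, 8 and 1 when adjusted over the list alone, median 0.21, adjusted p = 0.00186, and adjusted p = 0.426 with an estimated correlation) and fatty acid genes (7 and 0 of 16, median 0.21, adjusted p = 0.000828, and adjusted p = 0.426 with an estimated correlation) were also higher in that difference. Ribosome biogenesis genes were higher for 9 of 29, 10 when adjusted over the list alone (median 0.20, adjusted p = 0.0054, and adjusted p = 0.602 with an estimated correlation), lost without Tsc1-null 24 h replicate 2 (0.209). Oxidative phosphorylation genes were lower for 6 of 27 and higher for 3, with 8 and 3 when adjusted over the list alone (median -0.20, adjusted p = 0.0336, and adjusted p = 0.503 with an estimated correlation). That call was lost without Tsc1-null 24 h replicate 1 (0.19) or vehicle replicate 3 (0.0524) and without Tsc2-null vehicle replicate 1 (0.0505) or 2 (0.054). At 24 h alone 3669 genes differed, 1478 higher and 2191 lower, and at 2, 6 and 12 h 19, 755 and 2046 did.

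**Figure D3:**
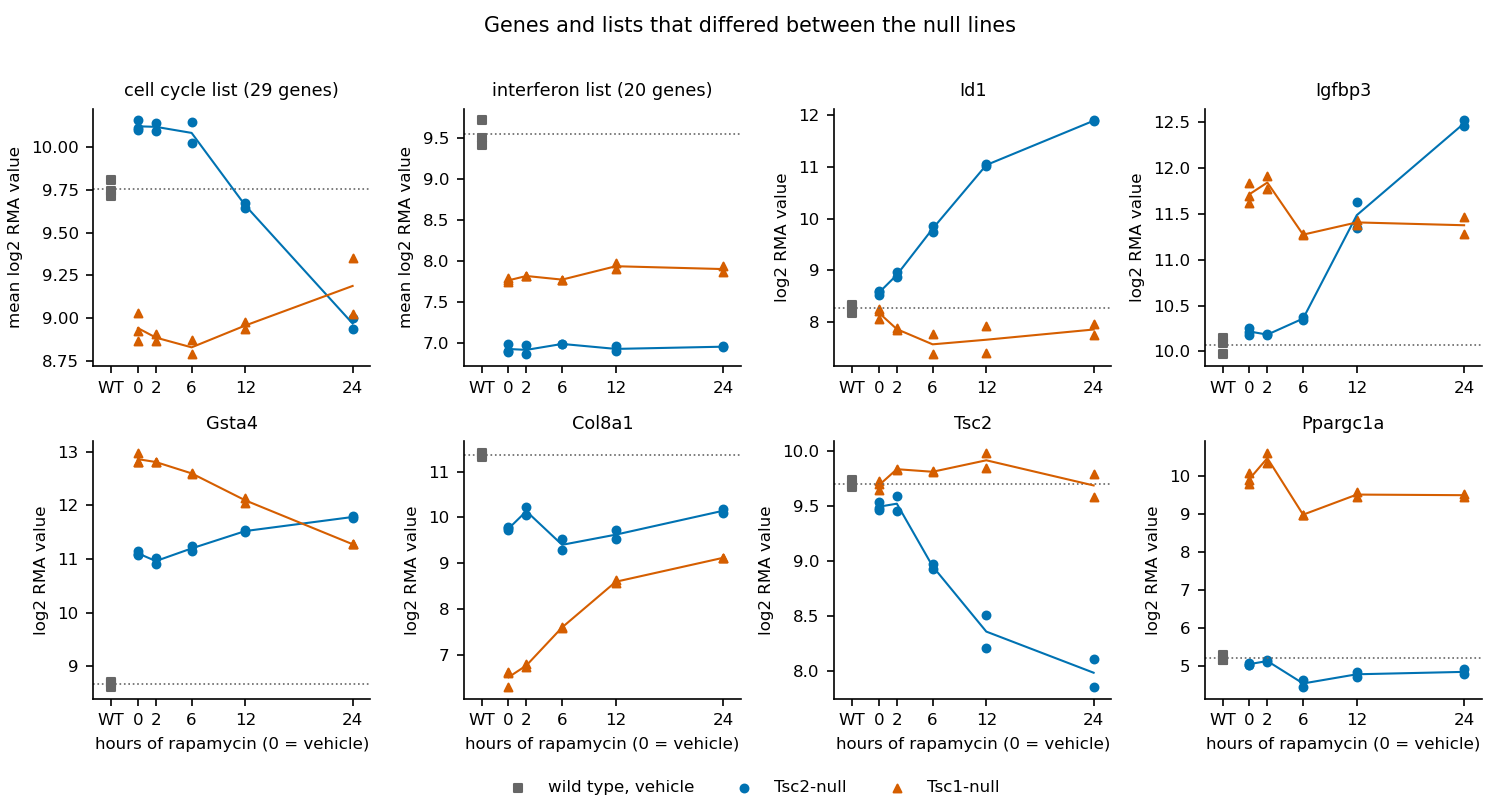
Log2 values (vertical axes) on every array against hours of rapamycin (horizontal axes) for the means of the cell cycle and interferon lists and for Id1, Igfbp3, Gsta4, Col8a1, Tsc2 and Ppargc1a. Squares are wild type, circles Tsc2-null and triangles Tsc1-null, lines join group means and the dotted line is the wild-type mean; Id1 reached 11.90 in Tsc2-null and stood at 7.86 in Tsc1-null cells at 24 h.

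Genes that differed from wild type in both null lines and moved back with 24 h of rapamycin in both were counted last. No minimum return was required. Without wild-type rapamycin arrays, whether that return depends on TSC loss was not tested. Genes higher in both and then lower in both numbered 864, where independent lists would give 29.8. They held 13 of 18 HIF targets (Fisher's exact test, adjusted p = 1e-12), 12 of 18 glycolysis genes (2.22e-11), 11 of 23 ATF4 targets (1.77e-08), 12 of 31 lysosome genes (4.76e-08), 9 of 16 fatty acid genes (5.05e-08) and 8 of 20 sterol genes (8e-06). Oxidative phosphorylation (7 of 27, 0.000739), pentose phosphate (4 of 8, 0.000953), tRNA synthetase (4 of 19, 0.0278) and p53 target lists (4 of 19, 0.0278) also passed. Fisher's test takes co-regulated genes as independent, so these p-values may be too small. The 0 of 29 cell cycle and 0 of 20 interferon genes in the set lay within chance (1.38 and 0.95 expected, Fisher's exact p = 0.401 and 0.623). The set held Vldlr, Egln3, Rnf128, Tmem45a, Prelid2 and Cd24a, with wild-type levels of 4.67 to 6.64. Vldlr went from 6.08 ± 0.15 in wild type to 9.88 ± 0.02 and 10.73 ± 0.08 in the null lines (n = 3 each) and to 7.22 ± 0.21 and 9.44 ± 0.10 with rapamycin (n = 2 each). Egln3 went from 6.64 ± 0.09 to 9.90 ± 0.06 and 9.90 ± 0.07 and then to 7.81 ± 0.09 and 7.74 ± 0.08. Cd24a, 6 and 7.68 above wild type, fell with -0.40 and -0.30 after rapamycin. Those calls were lost without Tsc2-null 24 h replicate 2, Tsc1-null vehicle replicate 1 (0.189) or 2 (0.0763), or Tsc1-null 24 h replicate 1 or 2. Genes lower in both and then higher in both numbered 508, where independent lists would give 16.4. They held 6 of 20 serum-response genes (adjusted p = 0.000161), 5 of 12 smooth muscle markers (0.000161), 5 of 19 ribosomal proteins (0.00118) and 5 of 29 matrix genes (0.00712), and also Ccl2, Ccn2, Dusp6, Egr1, Fgf7 and Plscr2. The chemokine gene Ccl2 went from 13.38 ± 0.17 to 10.46 ± 0.08 and 7.50 ± 0.28 and then to 12.23 ± 0.07 and 8.80 ± 0.21. Taken line by line, 1977 of the 4295 genes higher in Tsc2-null cells (46%) fell at 24 h, against 778.5 of independent lists, and 1895 of 3870 (49%) did in Tsc1-null cells, against 696.2. The null vehicle arrays entered both sides with opposite signs, with correlations across genes of -0.305 and -0.352 where simulation gave -0.462 and -0.411, and covariances of -0.097 and -0.0821 where it gave -0.0055 and -0.0045. Between the lines, which shared no array at 24 h, 1225 genes were higher and 1895 lower in both, against 368.1 and 592.2 of independent lists. In 100 simulations of unchanged groups with those shared arrays, the highest count in either set was 0. Those groups held no real differences, so that count does not show what sharing adds to them. The within-line covariances lie far beyond the simulated ones (SD 0.0046 and 0.0036). That argues against the shared vehicle arrays as the main source of the within-line excess. A smaller part may still come from them, and the excess is not called reversal by rapamycin.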

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

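Of the tests below, those on the Tsc2 probe set and on the cell cycle list were chosen only after the result was seen.

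Interferon-response genes were lower in both null lines than in wild type, the list mean by 2.61 (95% interval 2.49 to 2.73) in Tsc2-null and 1.78 (1.65 to 1.90) in Tsc1-null cells. If this were an mTORC1 output that rapamycin turns back, the list mean would rise by a like amount after 24 h of rapamycin, and the larger rise was 0.14 (0.00 to 0.27), which argues against it at that time. Macrophages or other blood cells in the wild-type plates would raise all their abundant transcripts, and the larger wild-type excess of the macrophage list mean was 0.06 (-0.06 to 0.17), with Lyz2 at 6.57, 6.53 and 6.58 and Tyrobp at 6.25, 6.14 and 6.09 in wild-type, Tsc2-null and Tsc1-null cells. Csf1r (8.18, 8.30 and 7.86) and Cd14 (8.60, 7.88 and 9.69) each ran in that direction against 1 null line and the other way against the other, so the list as a whole argues against that too. What stays open, and was not tested, is a difference between the lines themselves or an effect of the TSC genes that rapamycin does not turn back within 24 h.

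Cell cycle genes fell after 24 h of rapamycin in Tsc2-null cells (list mean -1.15, 95% interval -1.31 to -0.99) and not in Tsc1-null cells (0.25, 0.09 to 0.41, from 24 h arrays at 9.02 and 9.35, with the list's call lost without replicate 2, 0.104). Scaling between arrays would close the gap under another scaling, and the smallest gap over 3 other scalings was 1.41 (1.25 to 1.56), beside 1.40 as deposited, which argues against it. A starting level in the Tsc1-null line already at the level reached in the Tsc2-null line cannot be told apart from a different response, because the Tsc1-null vehicle level minus the Tsc2-null 24 h level was -0.03 (-0.19 to 0.13). The list mean was 8.94 ± 0.08 (n = 3) and 8.97 ± 0.05 (n = 2) in those groups. Intact p53 and the way of immortalization, which differ between the lines, were not tested.

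The Tsc2 probe set fell after rapamycin in Tsc2-null cells and not in Tsc1-null cells, by a 24 h difference between the lines of 1.51. Scaling between arrays would change that difference, and the smaller value under quantile normalization and median centring was 1.52, which argues against it. A dim probe set near background would rank low, and the lowest rank on the vehicle arrays was percentile 78.9 among all genes, which argues against that as well. What the probe set reads from the deleted allele was not tested, and no technical explanation beyond these was weighed.

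The null lines differed from each other under vehicle, by a direct test, in 7879 genes, and of the 10 splits of those 6 arrays 1, the real one, called as many, with 0 the highest of the other splits. The 8178 genes called between Tsc2-null and wild type and the 7646 between Tsc1-null and wild type likewise stood beside 0 as the highest other, and 10 splits are too few for a share under 0.05 in each. Tsc1-null minus Tsc2-null log2 differences under vehicle were 4.87 for Ppargc1a, 3.76 for Xist, 1.59 for Pdgfrb, 1.22 for Slc7a11, 1.11 for Myc, 0.84 for Ddit4, 0.82 for Pdgfra, 0.80 for Insig1, 0.79 for Asns, 0.67 for Cdkn1a, 0.55 for Vegfa, 0.50 for Pfkp, 0.43 for Srebf2, 0.42 for Mthfd2, 0.35 for Sqle, 0.28 for Scd1 and 0.17 for Pdk1. They were -0.22 for Fasn, -0.30 for Hif1a, -0.34 for Mdm2, -0.41 for Hk2, -0.59 for Slc2a1, -1.21 for Srebf1, -1.66 for Tsc1, -2.57 for Uty and -5.44 for Eif2s3y. Pdk1 was lost without Tsc1-null vehicle replicate 1 (0.0568) or 2 (0.175) and without Tsc2-null vehicle replicate 1 (0.129), 2 (0.0895) or 3 (0.0525), and Fasn without Tsc1-null vehicle replicate 2 (0.0965) or 3 (0.228) and Tsc2-null vehicle replicate 1 (0.179) or 2 (0.121). List medians in the same difference were -0.27 for glycolysis, 0.31 for sterol synthesis, 0.64 for ATF4 targets, 0.31 for tRNA synthetases, -1.04 for cell cycle and 0.64 for interferon response.

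The rapamycin time course differed between the null lines in 3911 genes by the F test. The 24 h change in Tsc1-null minus that in Tsc2-null cells was 2.22 for Col8a1, 1.51 for Tsc2, 0.83 for Ddit4, 0.74 for Srebf1, 0.74 for Pdgfrb, 0.74 for Cdkn1a (but -0.684 in the deposited ratio table), 0.61 for Tsc1, 0.58 for Pfkp, 0.47 for Myc, 0.45 for Fasn, 0.41 for Mthfd2, 0.39 for Sqle, 0.38 for Hif1a, 0.36 for Scd1 and 0.35 for Mdm2. It was -0.48 for Pdgfra, -0.68 for Insig1, -2.26 for Gsta4, -2.61 for Igfbp3 and -3.65 for Id1. List medians in that difference were 0.21 for glycolysis, 0.47 for sterol synthesis, 0.21 for fatty acid synthesis, 0.20 for ribosome biogenesis, -0.20 for oxidative phosphorylation and 1.49 for cell cycle.

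Several of these 24 h differences were lost when 1 array was left out, which leaves few arrays in a group. Without Tsc1-null 24 h replicate 2 these were Fasn, Hif1a, Mdm2, Mthfd2, Myc, Pdgfra, Scd1, Sqle and Tsc1. Without Tsc2-null 24 h replicate 2 they were Fasn, Mthfd2, Myc, Pdgfra, Scd1 and Sqle. Without Tsc2-null 24 h replicate 1 they were Hif1a, Mdm2 and Tsc1, and without Tsc1-null 24 h replicate 1 Sqle and Tsc1. Without Tsc2-null vehicle replicate 1 they were Fasn (0.0554), Hif1a (0.0587), Mthfd2 (0.0588), Scd1 (0.0522), Sqle (0.0611) and Tsc1 (0.0536), without replicate 2 Scd1 (0.0659) and without replicate 3 Mthfd2 (0.0726). Without Tsc1-null vehicle replicate 1 they were Mthfd2 (0.0774) and Tsc1 (0.0589), without replicate 2 Hif1a (0.0525), Mthfd2 (0.052) and Tsc1 (0.052), and without replicate 3 Fasn (0.0552), Scd1 (0.0735) and Sqle (0.0739).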

How the results depend on the processing

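Chosen only after the result was seen were the tests with the deposited ratio table and with array spread as a covariate. Of the results for named genes 3336 of 3529 kept direction and call when an array was left out, as did 1588 of 1632 list results, while 164 of 174 counts stayed within 1.5-fold of the reported count; quantile normalization kept 618 of 631 gene results, 523 of 599 held in the ratio table, and 215 of 288 list results held with the estimated correlation. The count of genes at 2 h in Tsc2-null cells, 400 as reported, was 606 after quantile normalization, 721 with array spread as a covariate and 228 with only the groups compared. In Tsc1-null cells at 2 h, 592 as reported, it was 934, 1136 and 234 under the same settings and 1355 with array weights, and at 6 h, 4094 as reported, it was 6488 with array weights. Leaving out 1 array gave 152 to 248 (Tsc2-null 2 h), 134 to 499 (Tsc1-null 2 h) and 2085 to 3802 (Tsc1-null 6 h). Lists called with an estimated correlation numbered 4 and 9 for Tsc2-null and Tsc1-null against wild type, 0 between the null lines, 2, 7 and 8 at 2, 6 and 12 h in Tsc2-null, 2, 7 and 10 in Tsc1-null cells, and 0 for the 24 h interaction, since camera then widens the spread of a list. With fry 20 lists were called for Tsc2-null against wild type and 20 between the null lines. At 2 h in Tsc2-null cells 12 lists were called with 64 added and 11 with trend and robust, and the ratio table called 3 between the null lines and 4 at 2 h in Tsc1-null cells. In the ratio table the ribosomal protein median at 12 h in Tsc2-null cells turned to -0.0478 and the 24 h interaction of Cdkn1a to -0.684. Apart from camera's estimate and the fewer arrays of the groups compared alone or of a left-out array, the cause was not tested.

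The replicate block called 378 genes at 2 h in Tsc1-null cells, against 592 without it. Replicate numbers did not pair arrays across groups: residual correlations of 113 same-number pairs ran from -0.405 to 0.548, 34 of them over 0.1, and 2 of 25 arrays correlated best with their own number. A left-out array leaves 1 array in a rapamycin group, which is then assumed to vary like the others. Signal over background limits what dim probe sets can show, and a difference from a level near background, such as 5.21 for Ppargc1a in wild type, is read as a lower bound. With the dimmest 40% of genes left out 16 of 228 list results lost their call, and the cause was not tested.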

Other observations

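Of the tests below, those on p53 targets were chosen only after the result was seen.

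Single markers of other lineages differed between the lines although their lists were not called. The epithelial cadherin gene Cdh1 rose from 3.85 ± 0.18 in wild type, near background, to 8.04 ± 0.12 in Tsc2-null cells (n = 3 each), while the keratin gene Krt18 fell from 9.30 ± 0.14 to 7.70 ± 0.04 there and to 5.12 ± 0.07 in Tsc1-null cells. Lpl, the lipoprotein lipase gene, stood at 11.96 ± 0.04 in Tsc2-null and 6.19 ± 0.10 in Tsc1-null cells, the first 3.96 (SE 0.17) above wild type and the other near background. The fatty acid binding protein gene Fabp4 rose from 5.32 ± 0.40, near background, to 8.46 ± 0.16 in Tsc1-null cells and fell to 5.57 ± 0.01 (n = 2) after 24 h of rapamycin. The intermediate filament gene Nes fell from 9.85 ± 0.10 to 8.06 ± 0.18 and 8.41 ± 0.06 in the null lines. Krt18 rose by 2.09 (SE 0.13) and Krt14 by 1.25 (SE 0.13) after 24 h of rapamycin in Tsc2-null cells.

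The p53 targets as a list mean stood at 8.85 in Tsc1-null and 8.42 in Tsc2-null cells under vehicle. A candidate explanation is intact p53 in the Tsc1-null line, which would put that mean above both p53-null lines. It was higher by 0.35 (95% interval 0.27 to 0.44) than in wild type and by 0.43 (0.34 to 0.51) than in Tsc2-null cells, but camera gave adjusted p = 0.222 and 0.0614 for the list against other genes. Perp carries most of the difference from wild type. Without it the differences were 0.06 (-0.03 to 0.15) and 0.19 (0.10 to 0.28), while leaving out any other member gave 0.27 to 0.50 and 0.31 to 0.58. Since p53 status, the Tsc1 deletion and immortalization go together in that line, p53 cannot be told apart from another difference between the lines, and the means are not read as a shift of the p53 targets as a group.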
